A study of Bos taurus with 11 samples.

How the data were processed

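Peripheral blood mononuclear cells of 5 Ladakhi and 6 Sahiwal female cattle were profiled on 1-colour Agilent bovine arrays, 1 animal per array. Per the labels' protocols, total RNA was extracted with Trizol, purified on columns with DNase treatment, amplified from a T7 promoter primer and labelled with Cy3. The labels do not say how the cells were isolated or how long the blood stood. Per the file headers, the deposited intensity values come from Feature Extraction, whose processed signal is the Cy3 intensity of a spot after background subtraction and spatial detrending, with a surrogate in place of signals not above background. Per the file headers, the Ladakhi slides were read on an Agilent scanner and extracted with version 12.0.1.1, and the Sahiwal slides were read on an Axon GenePix scanner and extracted with version 9.5.3.1. Each of the 4 slides holds a single breed, with 4 and 1 Ladakhi arrays and 4 and 2 Sahiwal arrays. The authors also deposited a table of log2 values centred so that each probe's median over the 11 arrays is 0. Its base and direction were checked against the scanner values, while its scaling between arrays is not stated. Each of its 11 columns matched a different array of the same breed than the one it is named after (correlation at least 0.9999 over detected probes), so it was used only for the breed comparison, as an alternative. Animal numbers in the report are those of the scanner files, and the numbering is unsettled. Its column medians ran from 1.60 to 2.32 in Ladakhi and from -0.73 to 0.00 in Sahiwal.

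From these files, control spots were left out, 294 spots with an outlier mark were set missing, spots of 1 probe were averaged, and log2 of the processed signal was taken minus each array's 75th percentile over the 43653 probes. This scale was fixed before the data were examined. It was kept although 12.3% of the spots were detected on the Ladakhi arrays on average, so that its reference lies at the background there, and the percentile over the probes detected on all 11 arrays was added as an alternative. A probe was tested where it was well above background on at least 4 arrays of either breed (17868 probes) and is called measured where this held in both (4048 probes). Saturated spots were kept, and leaving out probes with any was added as an alternative. They numbered 71 to 228 on the Sahiwal arrays and 0 on the Ladakhi arrays. Accessions of 26740 probes matched the gene table of assembly ARS-UCD2.0, used for names only, and 33485 probes had a symbol, of which 2176 were updated. Coordinates are those of the files, on HGSC Btau_3.1. A gene with several probes was represented by its brightest probe. Among 627 genes with at least 2 measured probes, 274 had probes of opposite sign and 33 had probes changed in both directions.

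Breeds were compared with limma 3.58.1 (lmFit and eBayes, both directions, Benjamini-Hochberg adjustment over the probes tested) in R 4.3.3, at an adjusted p of 0.05. Gene lists, 14 of pathways and 9 of cell types, were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Fry, which asks whether the genes of a list move on balance one way, was run on the genes measured in both breeds. It called 1 list, the HIF pathway regulators (adjusted p = 0.00139), and its mixed test called 14. That call rests on 3 measured genes, which camera did not call (adjusted p = 0.339). Over the 12 tested members of that list camera pointed to lower levels, also without a call (adjusted p = 0.679). Genes were named by a rule fixed beforehand: the 5 highest and 5 lowest changed genes detected on all arrays without overlap or saturation, the 2 measured members with the largest change in each pathway list, the 1 in each cell type list, and HIF1A, EPAS1, EGLN1 and VEGFA. Other list members named in the report, GAPDH, JUNB, FOSB, the chemokines and the genes on 1 to 3 Ladakhi arrays among them, were chosen after their values were seen. Counts adjusted over the list alone are the same as those over all probes except where the report gives both. On simulated data with known changes on the 17868 tested probes, the test recovered 1 of 50 probes changed by a log2 of 0.5, 3 of 50 at 1, 31 of 50 at 2 and 49 of 50 at 4, with 7 false calls among 17668 unchanged probes. With so few probes changed, the adjustment was stricter in the simulation than in the real comparison, where 7904 probes changed. These recoveries are therefore not those of the real comparison. The number of arrays and the dim Ladakhi signal limit the precision.

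Alternatives covered the background correction (normexp with offset 50 on the median signal, since the mean signal is missing from the Ladakhi files), scaling, filter, floor, outlier marks, slide as a random block, animal number as a block, array weights, the variance prior, a test against a log2 difference of 1, the value table, the mean of a gene's probes, and each array left out. Gene lists in the alternatives were tested with camera on the probes' moderated statistics, whose adjusted p for the ribosomal proteins is 0.0481 in the main setting. Mismatches between the breeds' genomes and the probe sequences were not analysed here.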

Results

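Total RNA of peripheral blood mononuclear cells, the lymphocytes and monocytes of the blood, was measured in 11 female cattle on 1-colour bovine oligonucleotide arrays with 43653 distinct probes. Ladakhi cattle, a native breed kept at high altitude, gave 5 arrays, and Sahiwal cattle, a breed of the low-lying plains, gave 6 arrays, with 1 animal per array. The Ladakhi arrays were much dimmer. Spots well above background numbered 5373 ± 1117 (SD, n = 5, range 4243 to 6608) of 43803 on the Ladakhi arrays and 18848 ± 1352 (SD, n = 6, range 17517 to 20574) on the Sahiwal arrays. The 75th percentile of the processed signal was 27.2 ± 4.93 (SD, n = 5) in Ladakhi and 259 ± 82.7 (SD, n = 6) in Sahiwal. A gene is called measured below where its probe lay well above background on at least 4 arrays of each breed. This held for 4048 probes, while a further 10038 probes met it in Sahiwal and lay above background on no Ladakhi array. Levels are log2 signals relative to each array's 75th percentile, and differences are Ladakhi minus Sahiwal.

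**Figure D1:**
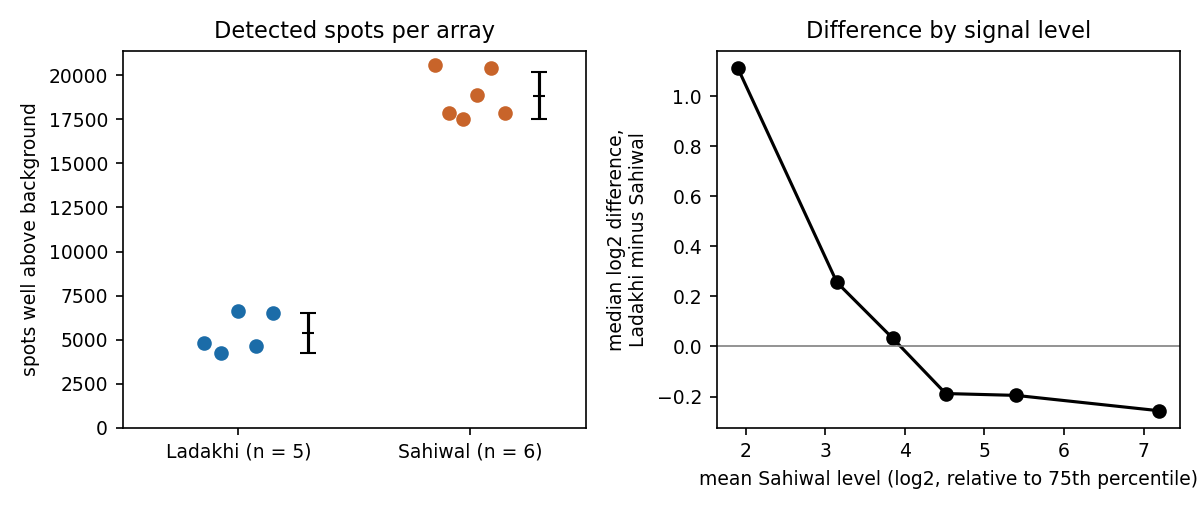
Left, spots well above background on each of the 5 Ladakhi and 6 Sahiwal arrays (points), with mean and SD (bars). Right, median log2 difference, Ladakhi minus Sahiwal, of the probes detected on all 11 arrays against their mean Sahiwal level, in 6 groups of 451 probes each. The difference fell from 1.11 in the dimmest group to -0.26 in the brightest. The Sahiwal level enters both axes with opposite sign, and probes dim in Sahiwal entered only if detected on all Ladakhi arrays. Such a fall can arise from these limits alone.

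The comparison asks how the blood cell transcriptome of cattle native to high altitude differs from that of cattle from low altitude. Among the genes measured in both breeds, Ladakhi cells had higher levels of the T cell and cytotoxic cell genes CD2 and CST7, of the glycolytic enzyme genes PKM and LDHA, and of the HIF pathway regulator genes EGLN2 and ELOB. They had lower levels of the early response genes IER5, DUSP1, JUNB and FOSB, of the inflammatory genes IL1RN and NFKBIA, of the MHC class II gene BOLA-DMB and of the myeloid genes LYZ, SPI1 and S100A8. The T cell genes CD3E, CD3G and CCR7, not counted as measured, were lower. The myeloid genes CEBPA, by its brightest probe, and FCER1G were higher. Of the 2581 genes measured in both breeds, 804 changed (31.2%), with 449 higher and 355 lower in Ladakhi (limma, Benjamini-Hochberg adjusted p under 0.05), and 595 of them differed by at least 2-fold. In 452 of the changed genes the breeds did not overlap. The chance rate of no overlap, 0.433%, holds for genes not selected by a call, so it is not a rate for the changed genes. Counted over all 17868 probes tested, 7904 changed. Of these, 6593 were not measured in both breeds, and 5099 lay above background on no Ladakhi array. The Ladakhi values of those 5099 are surrogate or dim signals, so their directions, 3443 higher and 1656 lower, are not read. Breed coincided with scanner model, image extraction version and slide on these arrays, so breed and platform cannot be told apart for any difference given here. Detection also favours one direction, because the lowest level that counted as above background averaged 1.80 in Ladakhi and -2.82 in Sahiwal. A gene below the Ladakhi limit in Sahiwal, as INHBC, ABI3, GPR171, ENG, CD2 and CST7 were, could therefore only be measured where it was higher in Ladakhi. In the other direction, genes well above background on 1 to 3 Ladakhi arrays were not counted as measured. Of 102 such list genes, 35 were lower and 10 higher, or 31 lower and 24 higher with dim signals raised to each array's lowest signal well above background. As the Ladakhi limit lies above that of Sahiwal, this raising understates lower and overstates higher differences. A gene with a Sahiwal mean below the Ladakhi limit can only come out higher after it. This held for all of the 24 higher genes, so no direction is read from their raised values. Differences given below for genes on 1 to 3 Ladakhi arrays are those after this raising, because their Ladakhi values rest partly on surrogate signals. Saturated spots occurred only on Sahiwal arrays, so that a lower gene with such spots is given as a minimum difference and a positive difference as an upper limit.

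Among changed genes detected on all 11 arrays, without overlap between the breeds and saturated on none, the 5 with the largest positive difference were INHBC, ITPR1, ABI3, GPR171 and CEBPA (positions are those of the probes on the array's own build, HGSC Btau_3.1). INHBC, a subunit gene of the activin and inhibin family (chromosome 5, 60470238 to 60470297), had a level of 6.32 ± 0.69 (SD, n = 5) in Ladakhi against -1.88 ± 0.34 (SD, n = 6) in Sahiwal. This difference of 8.20 (SE 0.33, adjusted p = 1.46e-09) rests on 1 probe. The probe named ITPR1 (chromosome 22, 22199276 to 22199334) differed by 5.27 (SE 0.48, adjusted p = 9.69e-06), but its sequence reads as 18S ribosomal RNA, recognised from general knowledge, and not as the ITPR1 calcium channel message. The 4 ITPR1 probes without that sequence lay above background on 0 Ladakhi arrays. ABI3, a regulator of actin assembly in blood cells (chromosome 19, 38557725 to 38557784), was 15.0-fold higher in Ladakhi, at 4.38 ± 0.18 (SD, n = 5) against 0.47 ± 0.34 (SD, n = 6). GPR171, a receptor gene expressed on T cells (chromosome 1, 118478029 to 118478088), was higher by 3.71 (SE 0.35), at 3.96 ± 0.57 (SD, n = 5) against 0.25 ± 0.61 (SD, n = 6). CEBPA, a myeloid transcription factor gene (chromosome 18, 43155580 to 43155639), was 10.4-fold higher by its brightest probe, while its other measured probe gave -0.59.

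Under the same limits, the 5 genes with the largest negative difference were CFDP2, RPL34, H3-5, TKT and UTP14A. CFDP2 (chromosome 27, 7418699 to 7418759) was 9.11-fold lower in Ladakhi, at 2.40 ± 0.71 (SD, n = 5) against 5.58 ± 0.45 (SD, n = 6), by the only one of its probes that was measured. The mean of its probes, 5 of which lay above background on 0 Ladakhi arrays, gave -0.31 (adjusted p = 0.421). RPL34, a protein of the large ribosomal subunit (chromosome 6, 18084330 to 18084389), was 6.38-fold lower. H3-5, a variant of histone H3 (chromosome 14, 19077576 to 19077635), was 6.09-fold lower, at 3.04 ± 0.88 (SD, n = 5) against 5.64 ± 0.69 (SD, n = 6). TKT, which encodes transketolase of the pentose phosphate pathway (chromosome 22, 48778331 to 48778390), was 5.30-fold lower, at 4.46 ± 0.40 (SD, n = 5) against 6.87 ± 0.47 (SD, n = 6). This is by its brightest probe, while its other measured probe gave -0.70 and did not pass. UTP14A, a factor of ribosome assembly (chromosome X, 6573140 to 6573198), was 4.14-fold lower by its brightest probe. Its 3 measured probes ran from -2.05 to -1.04, and 1 passed the threshold. Adjusted p-values of these 5 genes ran from 3.45e-05 for CFDP2 to 0.000967 for RPL34.

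Genes of the response to low oxygen moved in different directions. Of 10 measured HIF target genes, LDHA was higher in Ladakhi by 1.40 (SE 0.32, adjusted p = 0.0032), and PFKFB3, a regulator of glycolytic flux, and MXI1 fell by 2.76 and 1.18 on the log2 scale (adjusted p = 0.00564 and 0.024). The other 7 passed no threshold, and the median of the list was -0.34. Relative to the shift of all measured probes, 1 was higher and 5 lower with normexp, and 1 and 1 with quantile normalization. Of 8 further targets on 1 to 3 Ladakhi arrays, 4 were lower, HMOX1 by 1.69, NDRG1 and ALDOC by 1.18 and BNIP3L by 1.04. CA9 came out higher by 0.79, a direction that the raising sets, and had not passed before it (adjusted p = 0.209). Of 3 measured HIF pathway regulators, EGLN2, a prolyl hydroxylase that marks HIF proteins for degradation, was higher by 1.26 (SE 0.27), and ELOB, part of the ubiquitin ligase that removes them, by 1.49 (SE 0.27), with adjusted p = 0.00244 and 0.00086. RBX1 of the same ligase gave -0.44. HIF1A, EPAS1, EGLN1 and VEGFA were not measured in both breeds. Probes of HIF1A lay above background on at most 2 Ladakhi arrays, those of EGLN1 on at most 1, and those of EPAS1 and VEGFA on 0. The brightest probes of HIF1A and EGLN1 gave -0.08 and -0.47 before the raising and did not pass (adjusted p = 0.900 and 0.303). After it they gave 0.69 and 0.26 and did not pass either (adjusted p = 0.0674 and 0.455). Their Sahiwal means, 1.23 and 1.56, lay below the Ladakhi limit, so the raising sets that direction and none is read. No fold was obtained for EPAS1 and VEGFA.

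In energy metabolism, 3 of 15 measured glycolysis genes were higher and 0 lower, but 5 were higher and 4 lower with normexp relative to the shift of all measured probes. PKM, the pyruvate kinase gene, was 5.26-fold higher in Ladakhi, at 6.13 ± 0.42 (SD, n = 5) against 3.73 ± 0.60 (SD, n = 6). The difference of GAPDH, counted as the third with 1 Sahiwal array saturated, was at most 0.99. LDHA, also of this list, was 2.65-fold higher by its brightest probe, but the mean of its probes was not past the threshold (0.77, adjusted p = 0.133). Of 59 measured genes for oxidative phosphorylation, 10 were higher and 10 lower, with a median of 0.00. These counts depended on the scaling, with 17 higher and 4 lower after cyclic loess and 15 and 9 after quantile normalization, relative to the shift of all measured probes. Of 15 further genes on 1 to 3 Ladakhi arrays, 9 were lower and 1 higher, or 7 and 2 with the raised signals, where UQCRH was lower by 2.96. NDUFA7 and NDUFB10, both subunits of complex I, stood at opposite ends, with differences of 1.95 (SE 0.30) and -2.79 (SE 0.63). Adjusted over the list alone, 8 in place of 10 were lower. Of 6 measured genes for angiogenesis and vascular tone, the growth factor gene FGF2 was 7.90-fold lower and ENG, an endothelial co-receptor of TGF-beta, 3.64-fold higher. The ENG difference ended after cyclic loess (0.26, adjusted p = 0.658). Of 11 antioxidant genes, PRDX2, a peroxide-reducing enzyme of the cytosol, was higher by 1.57 (SE 0.35). The brightest probe of FTH1, the ferritin heavy chain, was saturated on all 6 Sahiwal arrays, so its difference of 1.63 is an upper limit and no direction is given. The 6 measured probes of FTH1 ran from -1.05 to 1.63, and their mean did not pass the threshold (0.42, adjusted p = 0.304).

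The early response and inflammatory genes that changed were mostly lower in Ladakhi. Of 11 measured immediate early genes, IER5, DUSP1, JUNB, FOSB and KLF2 were lower and JUND and KLF6 higher, with a list median of -0.62. Relative to the shift of all measured probes, 3 were lower and 2 higher after cyclic loess, and 4 and 1 after quantile normalization. IER5 stood at 4.16 ± 1.33 (SD, n = 5) against 7.05 ± 0.70 (SD, n = 6), at least a 7.40-fold difference with 1 Sahiwal array saturated (adjusted p = 0.000911). DUSP1, a phosphatase that switches off MAP kinases, stood at 3.74 ± 1.67 (SD, n = 5) against 6.19 ± 1.03 (SD, n = 6), a 5.49-fold difference (adjusted p = 0.00998). Of 7 inflammatory genes, IL1RN, the antagonist of the interleukin 1 receptor, was 9.11-fold lower (adjusted p = 0.00275) and NFKBIA, the inhibitor of NF-kappa-B, 3.83-fold lower (adjusted p = 0.018). The Sahiwal animals varied widely in both genes, with SDs of 1.60 and 1.57. The other 5, among them NFKB1, TLR2 and CCL5, did not pass the threshold. The interleukin gene IL1B, on 3 Ladakhi arrays, was lower by at least 3.46, with a Sahiwal SD of 2.56 and 1 array saturated. In 7 interferon response genes, ISG15 and MX1 fell by 1.67 and 1.36 on the log2 scale, with adjusted p = 0.0253 and 0.0238. Leaving out Ladakhi animal 1 or 4 ended the ISG15 call (adjusted p = 0.054 and 0.052), and leaving out Ladakhi animal 2 or 3 or Sahiwal animal 5 that of MX1 (adjusted p = 0.0669, 0.0681 and 0.0515). Cyclic loess ended both calls (adjusted p = 0.0715 and 0.131). Of 9 further genes of this list on 1 to 3 Ladakhi arrays, 0 changed before the raising. After it 4 came out higher, a direction that the raising sets, and 0 lower.

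MHC class II genes, which present antigen on B cells, monocytes and dendritic cells, had 4 of 7 measured members lower and 0 higher, with a median of -0.95. Relative to the shift of all measured probes, 1 was lower after quantile normalization or cyclic loess, 2 after median centring and 5 with normexp. BOLA-DMB was 2.55-fold lower, at 2.20 ± 0.65 (SD, n = 5) against 3.55 ± 0.46 (SD, n = 6), and BOLA-DQA1 and DSB were lower, at -1.23 and -0.95. BOLA-DRA, saturated on 2 Sahiwal arrays, was at least 4.18-fold lower with a wide Ladakhi spread (SD 2.43, n = 4, adjusted p = 0.0463). Without Ladakhi animal 5 the difference was -0.86, and leaving out any of the Sahiwal animals ended that call (adjusted p from 0.063 to 0.0799). CD74 was not past the threshold, at 0.53. The 3 further members on 3 Ladakhi arrays, BOLA-DQB, CTSS and BOLA-DOA, were lower by 2.49, 2.34 and 0.74. Of 13 genes of the unfolded protein response, ATF4, SYVN1, EIF2AK3 and SEC61B were lower and 0 were higher. ATF4, a transcription factor of the stress response, was at least 4.66-fold lower by its brightest probe, with 3 Sahiwal values and 2 Sahiwal arrays saturated, and a further measured probe gave 0.51. SYVN1, a ubiquitin ligase of the endoplasmic reticulum, was 3.48-fold lower by its only measured probe, while the mean of its probes, which takes in a probe not above background in Ladakhi, gave 0.25 (adjusted p = 0.564). Of 7 further genes of this list on 1 to 3 Ladakhi arrays, 0 were lower. ASNS came out higher, by 3.35 before the raising and 3.65 after it, and SDF2L1 only after it. The Sahiwal means of ASNS and SDF2L1, -1.67 and 1.39, lay below the Ladakhi limit, so the raising sets both directions. The earlier value of ASNS, above background on 2 Ladakhi arrays, rests partly on surrogate signals, so no direction is read from it. Of 13 heat shock genes, HSF1, the transcription factor of the heat shock response, was higher by 1.11 (SE 0.34) and the mitochondrial chaperone HSPA9 lower, at -0.90 (SE 0.33), while HSPA8, HSPA5 and HSP90AA1 lay within 0.13 of 0. Leaving out Ladakhi animal 1, 2 or 3 or Sahiwal animal 1, 2, 3 or 5 ended the HSPA9 call (adjusted p from 0.0515 to 0.113), and the mean of a gene's probes ended both calls (-0.05, adjusted p = 0.904 for HSPA9, and 0.56, adjusted p = 0.139 for HSF1). Neither heat shock gene passed when adjusted over the list alone, and for the unfolded protein response 3 in place of 4 did.

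Cytosolic ribosomal proteins were the only list of 23 that camera called shifted. Of 77 measured members, 27 were called higher and 5 lower, with a median of 0.62. However, 64 of the 77 were saturated on at least 1 Sahiwal array and 28 on all 6, so no direction of the list is given. Of the 13 saturated on none, 3 were higher and 2 lower, with a median of 0.16, and camera no longer called the list with saturated probes left out (adjusted p = 0.892). The sign of the median also turned with quantile normalization (-0.14, relative to the shift of all measured probes) and with the mean of a gene's probes (-0.27). Camera's adjusted p was 0.0409 with the preset correlation and 0.879 with an estimated correlation. RPL34 was lower, at -2.67 (SE 0.50). RPSA, saturated on 3 Sahiwal arrays, was lower by at least 2.46 (SE 0.58) by its brightest probe, while its other measured probe gave 0.09. Of 8 measured cell cycle genes 0 changed, and MCM5 and TK1, the largest of them, gave -0.69 (adjusted p = 0.157) and 0.55 (adjusted p = 0.177). The 3 further genes on 1 to 3 Ladakhi arrays came out higher with the raised signals, a direction that the raising sets. Before it, with Ladakhi values that rest partly on surrogate signals, 2 of them were higher, and ZWINT gave -1.08 (adjusted p = 0.0709).

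Marker genes of blood cell types also differed. Of 11 T cell markers, CD2, SKAP1, CD247 and CD4 were higher in Ladakhi and 0 lower, with a median of 0.85. CD2, an adhesion receptor of T and NK cells, was 5.48-fold higher, at 2.64 ± 0.32 (SD, n = 5) against 0.18 ± 0.50 (SD, n = 6), and CD3D and CD8A did not pass, at 1.08 and -0.04. Over the alternatives the CD2 difference ran from 0.93 to 2.57 and stayed past the threshold. The T cell list was not of 1 direction, because CD3E, CD3G and CCR7, on 2 or 3 Ladakhi arrays and so outside the 11, were lower by 1.59, 1.29 and 1.14 (adjusted p = 0.00723, 0.00422 and 0.0193). BLK, a kinase gene that B cells also express and the only gamma delta T cell marker of 2 past the threshold, was 2.10-fold higher. Of 7 NK and cytotoxic cell markers, the cystatin gene CST7 was 4.73-fold higher and the granulysin gene GNLY higher by 1.69, while the Fc receptor gene FCGR3A was lower, at -1.26. The FCGR3A call ended with quantile normalization, median centring, cyclic loess and the percentile over detected probes. With normexp 5 members were higher and 1 lower, relative to the shift of all measured probes. Adjusted over the list alone, 4 were higher and 1 lower. Monocyte markers had 3 of 10 members lower, LYZ, SPI1 and LGALS3, and FCER1G higher, with a median of -0.66. The FCER1G call ended after cyclic loess. FCN1, on 3 Ladakhi arrays, was lower by 2.44. LYZ, which encodes lysozyme, was 3.52-fold lower, at 5.12 ± 1.17 (SD, n = 5) against 6.93 ± 0.50 (SD, n = 6). The granulocyte marker S100A8, a calcium-binding protein of neutrophils and monocytes, was 4.64-fold lower (adjusted p = 0.00287). The platelet marker F13A1 was 2.71-fold lower, a call that ended after quantile normalization and after cyclic loess (adjusted p = 0.0514 and 0.0952). Among 6 B cell markers, 1 was higher and 1 lower, and 3 of 5 further markers on 1 to 3 Ladakhi arrays were lower. POU2AF1 was lower at -1.19 (adjusted p = 0.0389), a call lost when any array but that of Sahiwal animal 6 was left out (adjusted p from 0.0511 to 0.0836). HBB among the red cell markers (-0.62, adjusted p = 0.513) and CD83 among the dendritic cell markers (-1.78, adjusted p = 0.113) did not pass. Camera called none of these 9 cell type lists. For T cells its adjusted p among measured genes was 0.0692, and 0.782 with an estimated correlation.

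**Figure D2:**
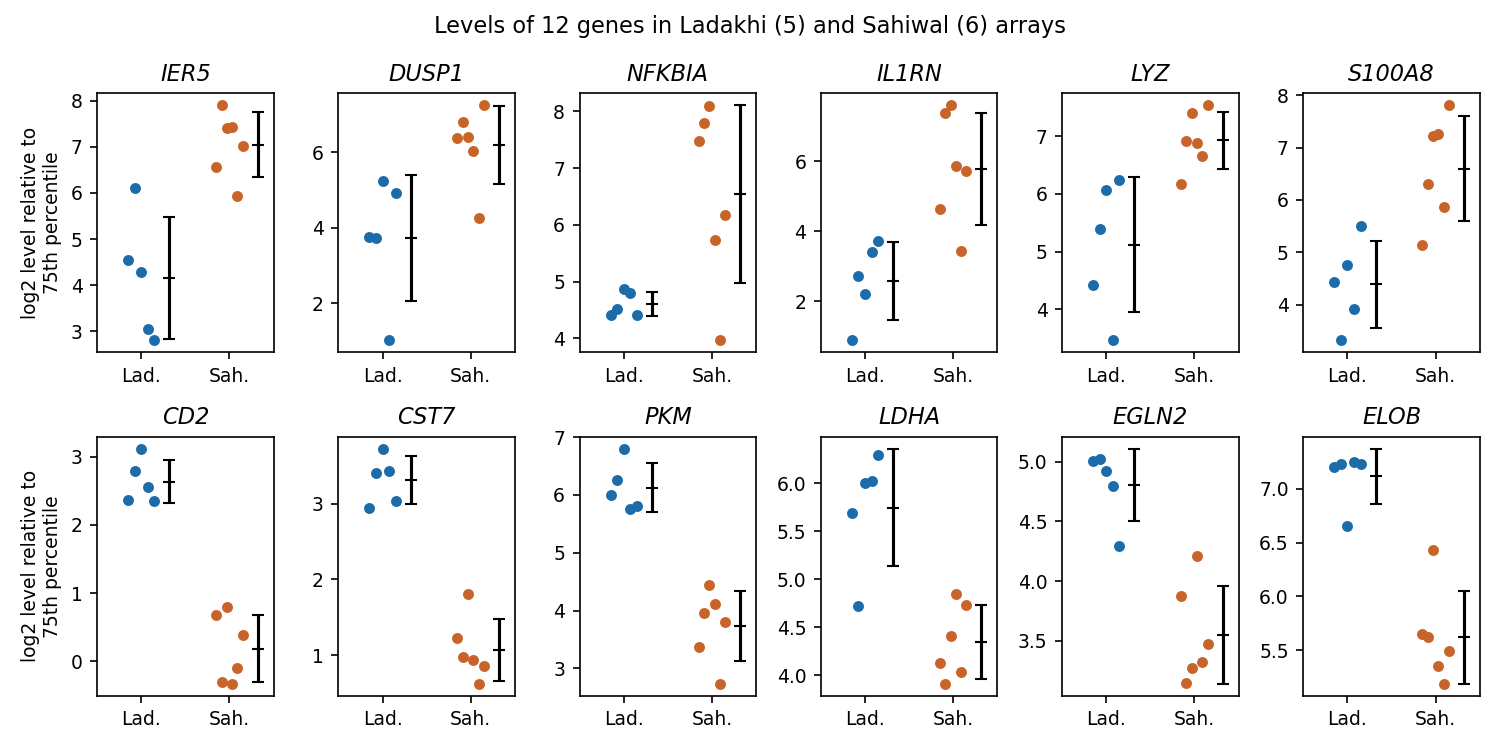
Levels of 12 genes (log2 signal relative to the array's 75th percentile) on the 5 Ladakhi and 6 Sahiwal arrays (points), with mean and SD (bars). The top row, from IER5 to S100A8, was lower in Ladakhi, and the bottom row, from CD2 to ELOB, was higher, by 1.26 for EGLN2 up to 2.45 for CD2.

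Other lists also had genes on 1 to 3 Ladakhi arrays that changed with the raised signals. The raising itself sets the direction of the higher ones. Higher and lower were 1 and 0 of 5 HIF pathway regulators, 1 and 2 of 6 inflammatory genes, 1 and 2 of 9 immediate early genes, 1 and 2 of 5 heat shock genes, 1 and 1 of 5 antioxidant genes, 1 and 3 of 5 T cell markers, 3 and 1 of 4 NK and cytotoxic cell markers, 0 and 2 of 4 monocyte markers, 0 and 1 of 2 granulocyte markers, 0 and 1 of 3 dendritic cell markers, 1 and 0 of 1 red cell marker and 2 and 0 of 4 platelet markers.

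Where all probes of a gene were not well above background on any Ladakhi array, only a bound on the difference was available. Among 102 such list genes, 13 had a bound above 1-fold. The antioxidant gene TXN was at least 2.34-fold lower in Ladakhi (bound 1.23 on the log2 scale, Sahiwal SD 0.37), and the monocyte marker AIF1 at least 2.48-fold (bound 1.31, SD 0.60). For the chemokine genes CCL4 and CXCL2, the antioxidant gene SOD2 and the granulocyte marker CSF3R, the bounds of 2.31, 1.76, 1.39 and 0.97 lay within the Sahiwal SDs of 3.58, 2.65, 1.62 and 2.28, so that single Sahiwal animals could lie below the Ladakhi limit. Over all genes, 3648 were not well above background on any Ladakhi array, and 42 of these had a bound of at least 2-fold. The bound sets the Sahiwal mean against the lowest level detected on the Ladakhi arrays.

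The 6 Sahiwal arrays lay on separate slides of 4 and 2 arrays, which gave the size of a difference between slides within a breed. None of 17852 probes changed between these slides by limma after Benjamini-Hochberg adjustment, and 755 had an unadjusted p under 0.05. The median absolute log2 difference was 0.339 between the slides and 0.823 between the breeds over the tested probes. Over the measured probes it was 0.293 and 0.642. The Sahiwal slides share scanner model and extraction version, so these values do not gauge a difference between platforms. Array profiles over the probes detected on all arrays separated by breed, and the first principal component held 48.5% of the variance.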

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

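Among the tests of this part, those on the 18S probe and on the other ITPR1 probes were chosen only after the results were seen. In 105 groups of arrays, each a measure in 1 breed, a single array stood apart from the rest 7 times. The groups were 89 of named genes, 2 of the T cell minus monocyte level and 14 of array quality. Chance gives about 1 in 20, or 5.25 of 105. Animal numbers are those of the scanner files, which the columns of the value table do not follow. ABI3 in Sahiwal animal 3 stood at 1.11, with the others from 0.19 to 0.49. RPL34 in Ladakhi animal 5 stood at 2.18, with the others from 4.44 to 5.26. ELOB in Ladakhi animal 3 stood at 6.65, with the others from 7.21 to 7.25. ENG in Ladakhi animal 1 stood at 3.76, with the others from 1.64 to 2.12. ATF4 in Ladakhi animal 5 stood at 6.61, with the others from 4.57 to 5.05. BOLA-DRA in Ladakhi animal 5 stood at 1.88, with the others from 6.34 to 7.01. The probe named ITPR1 in Ladakhi animal 2 stood at 6.92, with the others from 9.28 to 9.80.

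The probes named ITPR1 with 18S ribosomal RNA sequence were all higher in Ladakhi by 5.27, 8.61 and 8.84, with the 18S identity taken from general knowledge. Higher ITPR1 messenger RNA is argued against, since 0 of the 4 other ITPR1 probes lay above background on 4 or more Ladakhi arrays. The 9 measured probes annotated as ribosomal RNA had a median difference of -0.15 (SD 0.56 between arrays). This argues against a rise that takes in mitochondrial ribosomal RNA. As 7 of the 9 are mitochondrial, the median cannot speak on a rise in 18S and 28S ribosomal RNA alone. The 28S probe was higher by 1.41 (adjusted p = 0.0199). More 18S ribosomal RNA labelled in the Ladakhi samples remains a candidate explanation, since the probe annotated as 18S, which shares no stretch of 15 bases with the ITPR1 probes, was higher by 7.54 (SE 0.32, adjusted p = 2.63e-09). Whether such a rise came from RNA quality, from labelling or from the animals stays open, as each would follow breed here.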

How the results depend on the processing

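The 75th percentile over the probes detected on all arrays, the both-breed filter, cyclic loess and leaving out saturated probes were chosen after the data were seen. The share of higher against lower calls depended on the scaling, because the median difference of the measured probes, -0.03 in the main setting, was -1.52 with normexp, -2.99 with median centring, 0.18 with quantile normalization, -0.16 with loess and 0.15 with the filter on all arrays. Directions of single genes and lists below are relative to that shift. Probes changed numbered 7904 in the main setting, 17210 with median centring, 12893 with the floor, 34838 with no filter, 1009 with the filter on all arrays, 1166 with the both-breed filter, 1180 with loess and 755 when tested against a log2 difference of 1, where fewer probes were tested under the stricter filters and loess. Measured probes higher and lower, 718 and 593, became 81 and 3322 with normexp, 9 and 3949 with median centring, 1063 and 339 with quantile normalization, 648 and 361 with the filter on all arrays, and 87 and 30 against a log2 difference of 1. Relative to the shift they were 1052 and 852 with normexp, 693 and 432 with median centring, 849 and 512 with quantile normalization and 741 and 433 with loess. Genes changed, 3419, became 5775 with normexp, 8199 with median centring, 5522 with the floor, 636 with the filter on all arrays, 707 with the both-breed filter, 752 with loess and 309 against a log2 difference of 1. Measured genes higher and lower, 449 and 355, became 35 and 2154 with normexp, 3 and 2539 with median centring, 688 and 192 with quantile normalization, 418 and 218 with the filter on all arrays, and 44 and 8 against a log2 difference of 1. Other alternatives kept these counts within 1.5 times. Leaving out 1 array gave 6973 to 7743 probes, 627 to 753 higher and 452 to 635 lower probes, 3035 to 3360 genes, and 387 to 466 higher and 266 to 387 lower genes.

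Gene lists called, 1 in the main setting, numbered 3 with normexp, 5 with quantile normalization, 6 with median centring, 7 with the floor, 4 with the mean of a gene's probes, and 0 with outlier marks kept, the value table, the filter on all arrays, the slide block, the test against a log2 difference of 1, loess, saturated probes left out or an estimated correlation. Leaving out 1 array gave 0 to 3 lists. The cause of these moves was not tested. The ribosomal protein list turned to -0.14 with quantile normalization and to -0.27 with the mean of probes. Oxidative phosphorylation moved from 0.00 to 0.044 with quantile normalization, to 0.019 with the floor and to 0.24 with loess. Red cell markers moved from -0.016 to 0.013 with median centring. Lists called neither in the main setting nor in the alternative were compared by the spread of their median between arrays. With the mean of probes, MCM5 turned to 0.49, ATF4 to 0.0068 and SYVN1 to 0.25, and HBB turned to 0.045 with array weights. For SYVN1 and CFDP2 that mean takes in probes not above background in Ladakhi, and for the others the cause was not tested. Of 45 named genes 41 were called, and 36 of these kept the call whichever array was left out. The test against a log2 difference of 1 ended 28 of these calls, and cyclic loess ended 7, those of ENG, HSPA9, ISG15, MX1, BOLA-DRA, POU2AF1 and F13A1. Slides within Sahiwal gave 0 changed probes under every setting run. Animal numbers, as the scanner files give them, do not pair the breeds: the correlation of deviations of same-numbered animals ran from -0.051 to 0.023 in 5 pairs, and 0 pairs matched best, although the value table numbers the arrays otherwise, so the numbering is unsettled. With the animal number as a replicate block, 6907 probes, 2969 genes and 0 lists were called. Signal over background limits the comparison, since 22.7% of the probes detected in Sahiwal were detected in Ladakhi.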

Other observations

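Among the tests of this part, that on dim probes was chosen only after the results were seen. Messages encoded by the mitochondrial genome were mostly higher in Ladakhi. Of 24 such probes, a set chosen after its values were seen, 22 were measured, with a median difference of 1.42, and 18 of these were saturated on no array. Of the 18, 14 were higher and 0 lower, with a median of 1.67. Probes of ND1 and ND4, subunits of complex I, were higher by 1.01 to 4.27 and by 1.41 and 2.32, and ND4L by 2.97. Those of CYTB, the cytochrome b of complex III, ran from 1.15, which did not pass (adjusted p = 0.066), to 3.59. ND2, ND4L and a CYTB probe, with Sahiwal means of 0.26, 1.02 and 1.45, lay below the Ladakhi limit there. They could therefore only be measured where higher in Ladakhi. ATP6 had probes on both sides, at 1.91 and 1.42 and, with 2 Sahiwal arrays saturated, lower by at least 1.55. The COX2 probe without saturation did not pass the threshold (-0.68, adjusted p = 0.223). Nor did the COX3 probes without saturation (0.56 and 0.14, adjusted p = 0.292 and 0.799). Relative to the shift of all measured probes, the median of the 22 stayed between 1.19 with normexp and 1.46 with the percentile over detected probes. The nuclear genes of oxidative phosphorylation had a median of 0.00. Mitochondrial ribosomal RNA, at 7 measured probes, had a median of -0.23.

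The breed comparison was set against 100 of the 462 ways to split the 11 arrays into 5 and 6. The real split gave 7904 changed probes, of which 6593 were not measured in both breeds, and 3419 changed genes. The highest of the other splits gave 0 of each, so 1 of 100 splits was as large. The real split is also the split by scanner and signal strength, and every other split mixes the platforms. Counts of 0 in the other splits can arise from that alone. The test therefore says nothing on a breed difference apart from the platform. For gene lists, 95 of 100 splits called at least the 1 list of the real split, and the highest called 12, so chance is not excluded there.

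Among measured genes, the median breed difference of the T cell markers lay 1.51 above that of the monocyte markers. The T cell markers CD3E, CD3G and CCR7, on 2 or 3 Ladakhi arrays, are outside this set and were lower. On single arrays the median of 11 T cell markers minus that of 10 monocyte markers was -1.14 ± 0.67 (SD, n = 5) in Ladakhi and -1.91 ± 1.17 (SD, n = 6) in Sahiwal, a difference of 0.77 that did not pass an exact permutation test (p = 0.238, smallest possible 0.00433). After cyclic loess, which takes out a trend with signal strength, the difference was 1.39 between the list medians and 0.80 on single arrays (exact permutation p = 0.232). As the difference passed neither before nor after loess, the part of such a trend could not be decided. Scanner and extraction version stay open, as 0 slides hold both breeds, and so do cell shares and the animals themselves.

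Probes of the same gene often disagreed: the range of the measured probes of a gene had a median of 0.88. Position along the transcript may contribute, since in 1245 pairs the probe nearer the 5′ end had the larger breed difference by a median of 0.26 (SE 0.047). GC content may also contribute, as Spearman's rho between the difference in GC percent and in log2 difference was 0.31 (SE 0.035) over 1394 probe pairs, which are not independent replicates. For dim probes, rho between the difference in Sahiwal level and in log2 difference was -0.21 (SE 0.046). The Sahiwal level enters both quantities with opposite sign, so a negative rho can arise from that alone and decides nothing here. The rho of GC content reached the size set for it as a main explanation, but not by the margin of standard errors required. None of these values passed or excluded its size by that margin, so they cannot be told apart.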
